A study of Mus musculus with 14 samples.

How the data were processed

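RNA was measured in 10 libraries of mouse embryo fibroblasts, 6 wild-type and 4 p53-null, and p53 binding in doxorubicin-treated cells by chromatin immunoprecipitation and sequencing (ChIP-seq). Per the labels, RNA libraries were made by a 3' sequencing protocol from poly(A)-selected RNA, and the ChIP used the p53 antibody CM-5. The submitters' processing notes name DESeq, without a version, and the mouse build mm9. The aligner, the strand of the reads, the gene annotation, the peak caller, its threshold and its use of the background and p53-null libraries are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be separated.

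Each deposited RNA file holds 1 value for each of 20207 genes on a scale close to log2, with no header. The lowest deposited value was -0.0425 in every library and the highest was 24.43. The deposited values behave like variance-stabilised ones, since a doubling of reads added 0.9 units at 1 CPM, 1.09 at 10 CPM and 1.5 at 1000 CPM. All 10 libraries lay on 1 curve of reads divided by a library factor, and walking along this curve recovered whole reads. Of 23362 distinct values above a starting run of 250 reads, 99.91% lay within 0.01 of a whole read. The 22 others all stood at 143049 reads or more, at most 0.411 from a whole read. The recovered factors differed from median-of-ratios factors by at most a share of 0.0198. In simulated reads put through a known curve, 100% of values were recovered. Recovered reads are computed values and not a deposited count table, so count models were not used on them as the main test.

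The deposited peak list gives 3 values per peak. The enrichment is a ratio per the file headers, with no denominator stated. The next column is named as the -log10 of a q value per the file headers, but the deposited values run from 2.56 to 248643, too large for a q value on that scale, and no value of it was tested. The deposited rank is a score from 1 that follows the order of this column, except at 6 of 4784 steps between neighbouring ranks, and follows the enrichment less closely (Spearman -0.808 across peaks). The list had 5873 lines, of which 1088 repeated a peak and were dropped. No peak was assigned to a gene, because the annotation at hand is on another mouse build.

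Depth was the sum of recovered reads over the listed genes, 9768161 to 11770448 in wild-type and 18099506 to 25970157 in p53-null libraries. Ratios of few reads carry an exact 95% interval for counting error only, and reads without molecular identifiers are not independent molecules. Genes with at least 1 CPM in at least 2 libraries were tested (11177). Reads were scaled by trimmed means of M values (trims of 30% and 5%) computed in R 4.3.3, and log2 of CPM plus 0.5 was fitted with limma 3.58.1 using the trend option. The model had 1 mean per group over all 10 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Folds on this scale understate the change of genes near 0.5 CPM. Tests are two-sided. The 4 comparisons were treated against untreated wild type, treated against untreated p53-null, the difference of these responses, and untreated wild type against untreated p53-null.

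Lists of genes were tested with camera in limma at a preset correlation of 0.01, adjusted over 76 tests (19 lists with at least 5 tested members and 4 comparisons). Of the 22 list calls, only the p53 target calls in treated wild type and in the difference of responses held with an estimated correlation. With fry in place of camera, planned before the data were examined, there were 20 calls. Simulations with wild-type numbers paired were added after the results were seen. Endothelial, epithelial and sex chromosome markers had too few tested members. Members that passed were also counted adjusted over the list alone. In simulated data with these group sizes, 47% of 2-fold changes passed in the wild-type comparison, 26% in the p53-null comparison, 10% in the difference of responses and 26% between untreated genotypes. Of 4-fold changes, 100%, 91%, 74% and 98% passed.

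The groups, comparisons, scaling, thresholds, lists and the rule for named genes were fixed before the data were examined. The use of limma-trend in place of the count test first planned, the added 0.5 CPM and the 1 CPM filter were chosen afterwards. The rule named a panel of 7 genes in every comparison and the 10 largest rises and falls among called genes with average log2 CPM of 3 or more and no overlap between the libraries compared. It also named up to 4 members of each list by p, and the 5 peaks of best rank. Some genes that the rule takes are not reported here. Bok, Ctsd, Plk1, Spc25, Gtse1, Ulk2, Aldh4a1, Prkab1, Gadd45g, Wnt1, Zic5 and, between untreated genotypes, Polk are named outside this rule and were chosen after their values were seen.

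Replicate numbers were checked as pairs by correlating each library's deviations from its group mean. In wild type the same-number pairs correlated at 0.58, 0.34 and 0.61 and the other pairs at -0.5 to -0.02, so blocked counts, and blocked list tests where the call changed, are given beside the wild-type results. The p53-null groups have only 2 pairs, with a correlation of 0.38, and the untreated genotypes 0.17 and 0.24, which decides nothing. The sex markers of the p53-null libraries numbered 2 differed, so these numbers may not pair cultures, and blocked values of the difference of responses rest on that pairing. No pair of replicates was a copy, with correlations of deposited values from 0.958 to 0.982.

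Alternatives were limma-voom, 3 other scalings, other filters, thresholds and added CPM, a replicate block, only the groups compared, each library left out, the values as deposited, cyclic loess, reads thinned to equal depth, and the p53-null libraries numbered 2 left out. Figures and recovery used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The planned overlap of peaks with expression calls was not run, for want of an annotation on mm9. Reads of the ChIP libraries were not used here.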

Results

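Gene expression was measured by sequencing the 3' ends of poly(A) RNA from mouse embryo fibroblasts (MEFs) of strain 129/Sv. Wild-type and p53-null cells were left untreated or exposed to doxorubicin, a DNA-damaging topoisomerase II poison, at 0.2 µg/ml for 6 h. The wild-type groups held 3 libraries each and the p53-null groups held 2 each, 10 libraries in all. A list of p53 binding sites from doxorubicin-treated cells accompanied them. Levels are given as CPM, the reads of a gene scaled to a fixed library size, with the standard deviation (SD), and changes as log2 folds with the standard error (SE). The labels number the replicates without saying what each one is, so p-values measure the spread between these samples. The files give gene symbols only, and no coordinates of genes are printed because the sites and the annotation at hand are on different mouse builds.

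Untreated wild-type libraries 1, 2 and 3 held 9768161, 11701250 and 10032213 reads over the listed genes, and treated wild-type libraries 1, 2 and 3 held 11665491, 11770448 and 10602049. Untreated p53-null libraries 1 and 2 held 18099506 and 18698205 reads, and treated p53-null libraries 1 and 2 held 25252375 and 25970157. Between 13549 and 14547 genes had a read in the wild-type libraries, against 16435 to 17161 in the p53-null libraries. Every p53-null library was deeper than every wild-type library, so depth went with genotype in the comparison of untreated cells. The first principal component carried 47.4% of the variance and separated the genotypes, with wild-type libraries from -70.6 to -12.2 and p53-null libraries from 31.9 to 70.4. The next component carried 19.8% and separated treated wild-type libraries, at -54.8 to -30.5, from untreated ones, at 25.4 to 49.4.

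Reads of Trp53, the gene encoding p53, were present in both genotypes and were more abundant in the cells labelled p53-null. Untreated wild-type cells had 23.2 CPM (SD 2.73, n = 3) and untreated p53-null cells had 71.9 CPM (SD 3.25, n = 2), a wild-type minus p53-null log2 fold of -1.62 (SE 0.29, adjusted p = 0.00536). Reads of the 3' end check nothing about a deletion elsewhere in the gene. The Trp53 log2 fold with doxorubicin was 0.43 (SE 0.26, adjusted p = 0.322) in wild type and -0.98 (SE 0.32, adjusted p = 0.362) in p53-null cells. The p53 target gene Cdkn1a separated the genotypes in the other direction. Untreated wild-type cells held 686 CPM (SD 110, n = 3) of this gene, which encodes the cell-cycle inhibitor p21, against 30.4 CPM (SD 1.55, n = 2) in p53-null cells.

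Doxorubicin raised the canonical p53 targets in wild-type MEFs. Cdkn1a rose by a log2 fold of 2.73 (SE 0.18, n = 3 and 3, adjusted p = 3.01e-05), from 686 to 4537 CPM. Mdm2, which encodes the ubiquitin ligase that degrades p53, rose by 2.84 (SE 0.26, adjusted p = 9.84e-05), from 189 to 1381 CPM. Ccng1, encoding cyclin G1, rose by 3.17 (SE 0.28) and Bbc3, encoding the pro-apoptotic protein PUMA, by 2.45 (SE 0.28). Bax, a pore-forming BCL-2 family member, rose by 1.14 (SE 0.30, adjusted p = 0.034). Pmaip1, encoding NOXA, had 1 read over the untreated wild-type libraries and 110 over the treated ones, a depth-scaled ratio of 100 with a 95% counting interval of 17.6 to 4000. In the plot of Trp53 and its targets, no treated wild-type library overlapped an untreated one for these 6 genes.

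**Figure D1:**
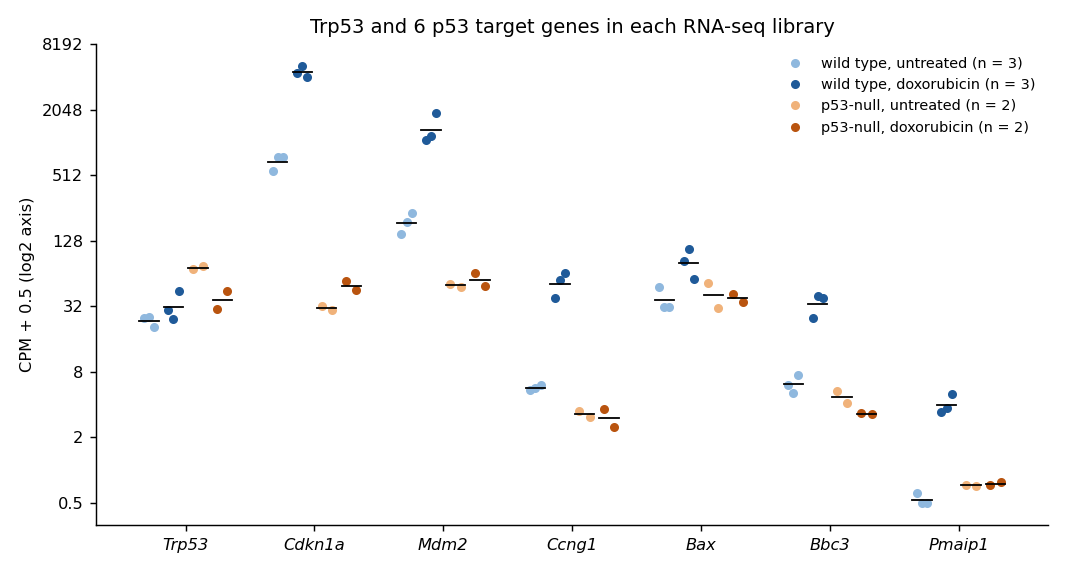
Levels of Trp53 and 6 p53 target genes in each of the 10 libraries, as CPM plus 0.5 on a log2 axis. Each point is a library and each bar the group mean of the log2 values. Treated wild-type libraries lie above untreated ones for the 6 targets. Arithmetic means, which the bars do not show, are 686 and 4537 CPM for Cdkn1a in untreated and treated wild type. Trp53 is highest in untreated p53-null cells, at an arithmetic mean of 71.9 CPM.

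Beyond this panel, the largest rises in wild type among genes of average log2 CPM of 3 or more included Hyal1, a hyaluronidase gene, at a log2 fold of 4.20 (SE 0.30, adjusted p = 3.52e-05). The transcription factor gene Scx rose by 3.81 (SE 0.31), and Dcxr, encoding L-xylulose reductase, by 3.75 (SE 0.28), from 76.2 to 1031 CPM. Icam1, encoding a leukocyte adhesion molecule, rose by 3.61 (SE 0.31), from 47.1 to 573.8 CPM. The other genes of this set were 4432412L15Rik (4.39), Cox6b2 (3.64), Nat6 (3.50), Iffo1 (3.40), Mmp15 (3.36) and Gm166 (3.29). Among the largest falls, Ccnb2, encoding cyclin B2, changed by -2.04 (SE 0.34, adjusted p = 0.00438), and Trib3, a stress-induced pseudokinase gene, by -2.17 (SE 0.29). Further falls were in Npas4 (-2.40), Cmklr1 (-2.35), H1f0 (-2.11), Fto (-2.06), Lrrc32 (-2.0), Ankrd1 (-2.0) and Gnl3 (-1.99).

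In total, 1406 of 11177 tested genes passed adjusted p under 0.05 in wild type, 896 higher and 510 lower with doxorubicin. At least a 2-fold change was fitted for 774 of the former and 330 of the latter. The split followed expression level. Genes of average log2 CPM under 1 had a median log2 fold of 0.24, with 239 higher and 20 lower. Those of 7 and above had a median of -0.07, with 58 higher and 77 lower. The list tests in wild type do not separate a list from the level of its genes. With the replicate number as a block, 2600 genes passed, among them all 1406. The count fell to 784 when only the wild-type libraries were fitted, and to 712 and 726 without untreated wild-type replicate 2 and 3. Without both p53-null libraries numbered 2, which share the estimate of the spread, it was 779. Bax lost its call under 10 of the alternatives and Fto under 7.

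Members of the p53 target list rose together in treated wild type. Of its 43 tested members 30 rose, 0 fell and 13 did not pass, and 36 rose when adjusted over the list alone. The median log2 fold was 1.95 (camera adjusted p = 1.86e-22, and adjusted p = 0.0013 with an estimated correlation). Besides Cdkn1a and Dcxr, the list held Ptprv, a receptor tyrosine phosphatase gene, which rose by 4.69 (SE 0.25, adjusted p = 1.29e-05) from 2.95 to 89.2 CPM.

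Apoptosis genes were raised in part, with 7 of 37 higher and 1 lower (9 and 1 adjusted over the list alone). The median was 0.33 (camera adjusted p = 0.0198, and adjusted p = 0.278 with an estimated correlation). Of the 7 raised, 6 also stand on the p53 target list, among them Bbc3 and Perp, a p53 effector gene at 2.14 (SE 0.23). The death receptor gene Fas had 3 reads in untreated and 58 in treated wild type, a depth-scaled ratio of 17.6 with a 95% counting interval of 5.74 to 88. The lower member was Bok, a BCL-2 family gene, at -1.04 (SE 0.21).

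Genes of the lysosome showed 10 of 48 members higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 0.23. The camera adjusted p was 0.0279, against an adjusted p = 0.58 with an estimated correlation. Members included Ctsf, a cathepsin gene, at 2.10 (SE 0.29), Fuca1, encoding a fucosidase, at 1.31 (SE 0.19), and Ctsd, encoding cathepsin D, at 0.86 (SE 0.22).

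Core autophagy genes did not pass as a list (median 0.38, camera adjusted p = 0.0762, adjusted p = 0.278 with an estimated correlation), and passed with the replicate block (adjusted p = 0.0413) and with fry (adjusted p = 0.00292), which tests members against no change and not against other genes. In this list 5 of 42 members rose and 0 fell, and 5 rose when adjusted over the list alone. Ulk1, encoding the kinase that starts autophagosome formation, rose by 1.73 (SE 0.20, adjusted p = 0.000428), from 23.3 to 78.8 CPM. Dram1, a lysosomal membrane protein gene, rose by 1.32 (SE 0.30, adjusted p = 0.018) from under 1 CPM, and Zfyve1, Wipi2 and Ulk2 were the other members. Autophagy is a theme the study is known to have drawn from these samples, so this list is not independent evidence of its direction.

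Genes of G2 and mitosis moved down in treated wild type. In this list 10 of 55 members fell and 3 rose (12 and 3 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 8.9e-05, adjusted p = 0.497 with an estimated correlation and adjusted p = 0.147 with fry). The falls included Ccnb2, the separase gene Espl1 at -1.49 (SE 0.22), the passenger complex gene Cdca8 at -1.48 (SE 0.30) and the kinase gene Plk1 at -1.65 (SE 0.43). The members that rose were Ckap2, a spindle protein gene, at 2.10 (SE 0.31), Spc25, a kinetochore gene, at 1.47 (SE 0.33), and Gtse1, also on the p53 target list, at 1.17 (SE 0.27).

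The other 14 lists did not pass in treated wild type at camera adjusted p from 0.0592 to 0.84. Blood and macrophage markers had a median of -1.06 with 0 of 14 members past the threshold (adjusted p = 0.0592). Their calls differed with the replicate block, where the adjusted p was 0.000386. With an estimated correlation and no block their camera adjusted p was 0.789. The macrophage receptor gene Csf1r went from 69 to 23.3 CPM and Tyrobp from 88.9 to 39.5 CPM, neither past the threshold. DNA replication genes (median -0.27, 1 higher and 3 lower of 55, 0 and 0 adjusted over the list alone) and interferon response genes (median 0.33, 3 higher of 32, 3 adjusted over the list alone) both stood at adjusted p = 0.0592. They passed with the replicate block at 0.026 and 0.0303. With an estimated correlation and no block their camera adjusted p was 0.452 and 0.855. The replication genes were Pold1, Tk1 and Gmnn, which were lower, and Rrm2, which was higher, and the interferon genes were Irgm1, Gbp3 and Tap1.

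In p53-null MEFs, no gene passed at adjusted p under 0.05 by limma-trend, and limma-voom also called 0 genes. At an unadjusted p under 0.05 there were 1255 genes, 595 higher and 660 lower, against 559 by chance, and the smallest adjusted p was 0.353. The log2 fold of Cdkn1a was 0.68 (SE 0.22, n = 2 and 2, adjusted p = 0.363), from 30.4 to 49.2 CPM, and that of Mdm2 was 0.17 (SE 0.31). The median log2 fold of the 43 p53 targets was -0.08, beside -0.07 for all genes. With 2 libraries a group, 26% of simulated 2-fold changes and 91% of 4-fold changes passed, so a change of 2-fold was mostly not detectable here. Without filtering low levels 2 genes passed, Wnt1 (13 reads untreated and 3 treated) and Zic5 (17 and 3). Without treated p53-null replicate 2 it was 1, Thbs1, at a log2 fold of -2.61 (adjusted p = 0.0325).

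Several lists passed as lists in p53-null cells although 0 of their members passed over all genes. Ribosomal protein genes (median 0.35, adjusted p = 8.97e-05), oxidative phosphorylation genes (0.31, adjusted p = 0.000694), DNA replication genes (0.30, adjusted p = 0.00208) and lysosome genes (0.27, adjusted p = 0.0403) lay higher with doxorubicin. Genes of G2 and mitosis (-0.48, adjusted p = 0.00198), immediate early genes (-0.36, adjusted p = 0.00192), unfolded protein and integrated stress genes (-0.41, adjusted p = 0.0146) and extracellular matrix genes (-0.38, adjusted p = 0.0394) lay lower. None of these 8 held with an estimated correlation, where adjusted p ran from 0.06 to 0.599, and matrix genes did not pass with library size alone (adjusted p = 0.0578). With fry 3 of the 8 passed, oxidative phosphorylation, immediate early and unfolded protein and integrated stress genes. The p53-null folds also ran with expression level, from a median of -0.26 under an average log2 CPM of 1 to 0.15 at 7 and above, and these list tests do not separate a list from its level. Adjusted over the list alone, 6 immediate early genes and 1 matrix gene were lower. Examples of those were Egr2, a zinc finger factor gene, at -1.41 (SE 0.36), and Thbs1, encoding thrombospondin 1, at -1.92 (SE 0.34, adjusted p = 0.353 over all genes).

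The test of the difference between the genotypes' responses found the p53 targets stronger in wild type. The wild-type minus p53-null response was 2.05 (SE 0.29, adjusted p = 0.00709) for Cdkn1a and 2.67 (SE 0.40, adjusted p = 0.00898) for Mdm2. It was 3.30 (SE 0.44) for Ccng1, 2.96 (SE 0.44) for Bbc3 and 2.85 (SE 0.36) for Pmaip1, a value that depends on the 0.5 CPM added before the log. In the same test Bax did not pass at 1.22 (SE 0.48, adjusted p = 0.187) and Trp53 did not at 1.41 (SE 0.41, adjusted p = 0.0976). Ckap2 rose in wild type from 4.79 to 21.9 CPM and had 48.6 and 17.8 CPM in untreated and treated p53-null cells, where its log2 fold of -1.52 (SE 0.38, adjusted p = 0.353) did not pass. The difference was 3.62 (SE 0.49). Cmklr1 showed the opposite sign at -1.91 (SE 0.39, adjusted p = 0.0374), with 34.8 and 6.47 CPM in untreated and treated wild type and 14.4 and 10.6 CPM in p53-null cells. Tk1, encoding thymidine kinase 1, fell in wild type from 268 to 147 CPM and had 150 and 265 CPM in untreated and treated p53-null cells, where it did not pass (adjusted p = 0.362). The difference was -1.72 (SE 0.35, adjusted p = 0.0359).

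For 261 genes the response differed by genotype, 211 with a higher and 50 with a lower wild-type response. Of the 211, 201 also rose in wild type, and of the 50, 44 also fell there. The p53-null fold was above 0 for 45 of the 50 and below 0 for 134 of the 211. Over all genes, 44.7% had a p53-null fold above 0 and 55.3% one below. No p53-null fold passed alone, and an opposite one adds to the difference by construction. The 896 genes raised in wild type had a median log2 fold of 1.41 there and 0.05 in p53-null cells, and 478 of them (53.3%) had a positive p53-null fold, against 44.7% of all genes. Across genes, which are not independent replicates, the 2 responses had a Pearson correlation of -0.009. With the replicate block 1076 genes passed, a count that pairs p53-null libraries numbered 2 although their sex markers differed (216 Y-linked reads untreated and 15 treated). Of the calls, 91% were higher with library size alone, 71.9% with median-of-ratios scaling, 74% with the values as deposited and 65.6% with the replicate block. The count was 169 with upper quartile scaling, where 95.3% were higher against 80.8% as reported. It was 159, 99 and 101 without treated wild-type replicate 1 and untreated wild-type replicates 2 and 3, and 38, 51, 70 and 86 without untreated p53-null replicates 1 and 2 and treated p53-null replicates 1 and 2. Of the 26 genes named for this comparison, Bax and Trp53 had no call as reported, and each of the 24 others lost its call under at least 1 alternative. The fit without both p53-null libraries numbered 2, with 1 library left in each p53-null group, kept none of these calls.

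**Figure D2:**
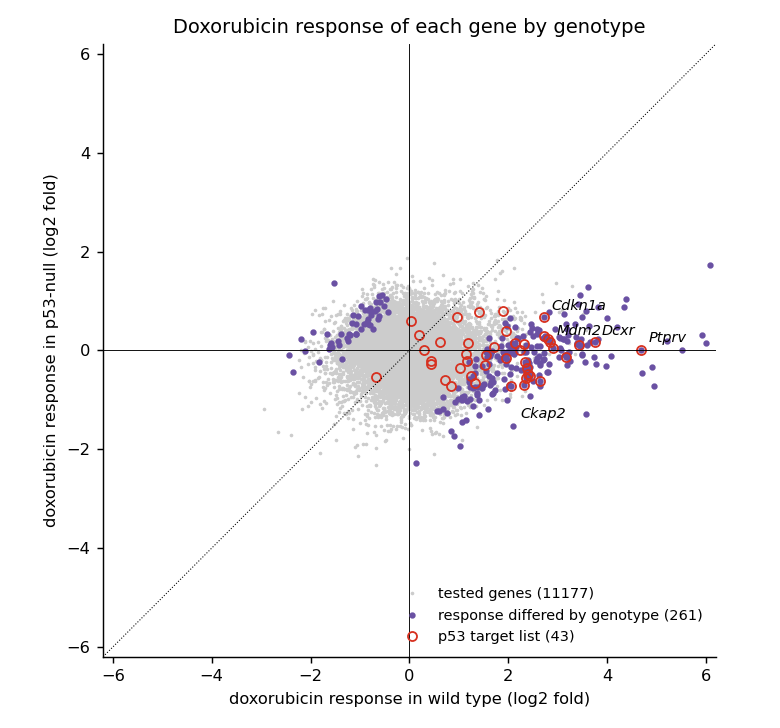
Log2 fold with doxorubicin of 11177 genes in wild type (x axis) and p53-null cells (y axis), with the 261 genes whose response differed in purple and the 43 p53 targets circled in red. The p53 targets spread along the x axis with a median of 1.95 and stay near 0 on the y axis with a median of -0.08.

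Among the lists, p53 targets differed most between the responses, with 18 of 43 members stronger in wild type and 0 weaker (29 and 0 adjusted over the list alone). Their median difference was 1.99 (camera adjusted p = 1.58e-18, and adjusted p = 0.0013 with an estimated correlation). Immediate early genes had a median of 0.80 (adjusted p = 0.0394, and adjusted p = 0.452 with an estimated correlation), with 1 of 42 past the threshold and 10 higher and 2 lower adjusted over the list alone. That member was Dusp6, a phosphatase gene of the ERK pathway, at 2.23 (SE 0.50). DNA replication genes had a median of -0.38 (adjusted p = 0.000877, and adjusted p = 0.278 with an estimated correlation), with Tk1 the 1 member of 55 past the threshold and 8 lower adjusted over the list alone. Ribosomal protein genes had a median of -0.34 (adjusted p = 0.00792, and adjusted p = 0.546 with an estimated correlation). Their 1 member past the threshold, Rpl23a, went the other way at 2.04 (SE 0.27). The difference of responses ran with expression level, from a median of 0.54 under an average log2 CPM of 1 to -0.22 at 7 and above, which these list tests do not separate from the lists. With fry the replication and ribosomal lists did not pass (adjusted p = 0.0754 and 0.43). The other 15 lists did not pass, at adjusted p from 0.0592 to 0.817. Among them were lists called in treated wild type. These were lysosome genes (median 0.04, adjusted p = 0.697), G2 and mitosis genes (-0.25, adjusted p = 0.291) and apoptosis genes (0.34, adjusted p = 0.141, against 0.0197 with fry). Core autophagy genes also did not pass, with 0 of 42 members past the threshold, also adjusted over the list alone. Their adjusted p was 0.648, against adjusted p = 0.0291 with fry. Ulk1 stood at 1.11 (SE 0.31, adjusted p = 0.0884) and Dram1 at 1.83 (SE 0.47, adjusted p = 0.0741). Blood and macrophage markers (median -0.94, adjusted p = 0.299, and adjusted p = 0.861 with an estimated correlation) passed with the replicate block at 0.00921.

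**Figure D3:**
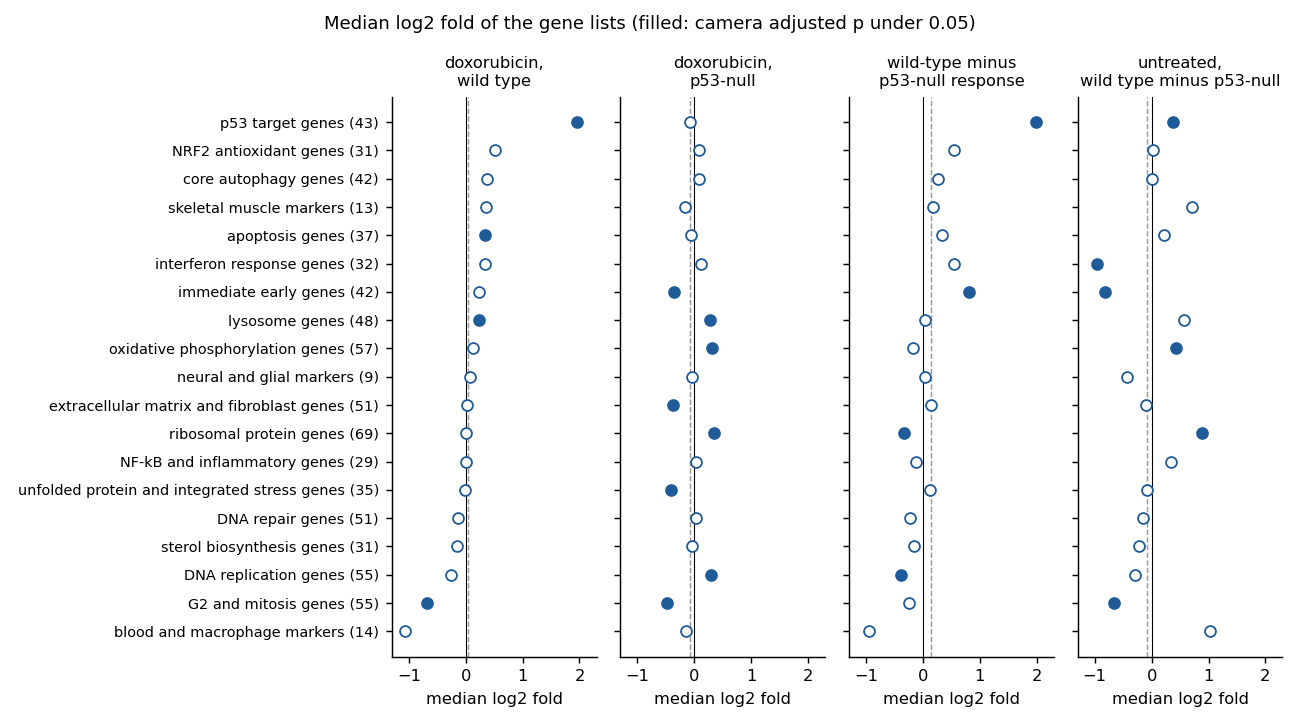
Median log2 fold of 19 gene lists (tested members in brackets) in the 4 comparisons; filled points passed camera at adjusted p under 0.05, and the dashed line is the median of all genes. The p53 target list reaches 1.95 in treated wild type and -0.08 in treated p53-null cells; ribosomal protein genes reach 0.89 in the comparison of untreated cells.

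The comparison of untreated cells asks which genes differ with the p53 genotype without added damage. Sex markers went in part with genotype in these libraries. Untreated p53-null libraries 1 and 2 had 207 and 216 Y-linked reads and 22 and 15 reads of Xist. Untreated wild-type libraries 1, 2 and 3 had 166, 0 and 2 Y-linked reads and 82, 86 and 161 reads of Xist. Sex or embryo of origin therefore cannot be fully told apart from genotype here. Cdkn1a had the largest fitted log2 fold of wild type over p53-null cells, 4.46 (SE 0.21, n = 3 and 2, adjusted p = 1.1e-06), on a scale that understates genes near the added 0.5 CPM, and Mdm2 was higher by 1.90 (SE 0.29, adjusted p = 0.00279). Ephx1, encoding microsomal epoxide hydrolase, was higher by 4.10 (SE 0.68), from 3.69 CPM in p53-null to 77 CPM in wild type. Sod3, encoding extracellular superoxide dismutase, was higher by 3.36 (SE 0.79), and the matrix metalloproteinase gene Mmp3 by 3.54 (SE 1.13, adjusted p = 0.0371). The rest of this set was Rps4x (3.76), a ribosomal protein gene that may share reads with its copies, 1810046J19Rik (3.66), Idh3g (3.62), Polr2h (3.59), Lman2l (3.47) and 6330578E17Rik (3.27). These 6 genes and Mmp3 also varied between wild-type libraries, being far lower in treated replicate 2 than in the other wild-type libraries. Idh3g stood there at 5.77 CPM, against 46 and 117.8 CPM in treated wild-type replicates 1 and 3 and 4.90 and 8.92 CPM in the untreated p53-null libraries. Mmp3 stood at 2.14 CPM, against 28.9 and 78.4 CPM and 1.97 and 2.68 CPM. A dependence on p53 is not shown for these genes.

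The largest differences ran the other way. Tusc5 stood at 2.62 CPM in untreated wild type and 2110 CPM in untreated p53-null cells, a log2 fold of -9.39 (SE 0.36, adjusted p = 5.01e-07). Lyrm4, an iron-sulfur cluster assembly gene, stood at 1.88 and 973.9 CPM (-8.67, SE 0.33), and Ifnar1, encoding a chain of the type I interferon receptor, at 13.3 and 1328 CPM (-6.60, SE 0.23). Sox8, a SOX family transcription factor gene, was lower in wild type at -6.05 (SE 0.28). The others were Rab3b (-6.20), Efha2 (-6.11), AI593442 (-5.82), Rdh13 (-5.69), Zfp26 (-5.65) and Pdcd4 (-5.51). A dependence on p53 is not shown for this set either, since sex, embryo of origin and library batch cannot be fully told apart from genotype here.

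In this comparison 3705 of 11177 genes passed, 1426 higher and 2279 lower in wild type, with 901 and 2091 at 2-fold or more. The split moved with the scaling of the libraries. With library size alone 517 were higher and 3339 lower, since the median of all genes then shifted by -0.35, and with upper quartile scaling, a shift of -0.16, there were 937 and 2573. Median-of-ratios scaling gave 1718 and 2047, and the values as deposited gave 1627 and 1883. The split also followed expression level. Genes of average log2 CPM under 1 had a median of -0.62, with 41 higher and 626 lower, and those of 7 and above had a median of 0.42, with 333 higher and 58 lower. Cyclic loess, which removes trends with level by construction, gave 2469 genes, 1109 higher and 1360 lower. The count fell to 422 and 492 without untreated p53-null replicate 1 and 2, to 2246 and 1750 without untreated wild-type replicate 2 and 3, and to 216 without both p53-null libraries numbered 2.

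**Figure D4:**
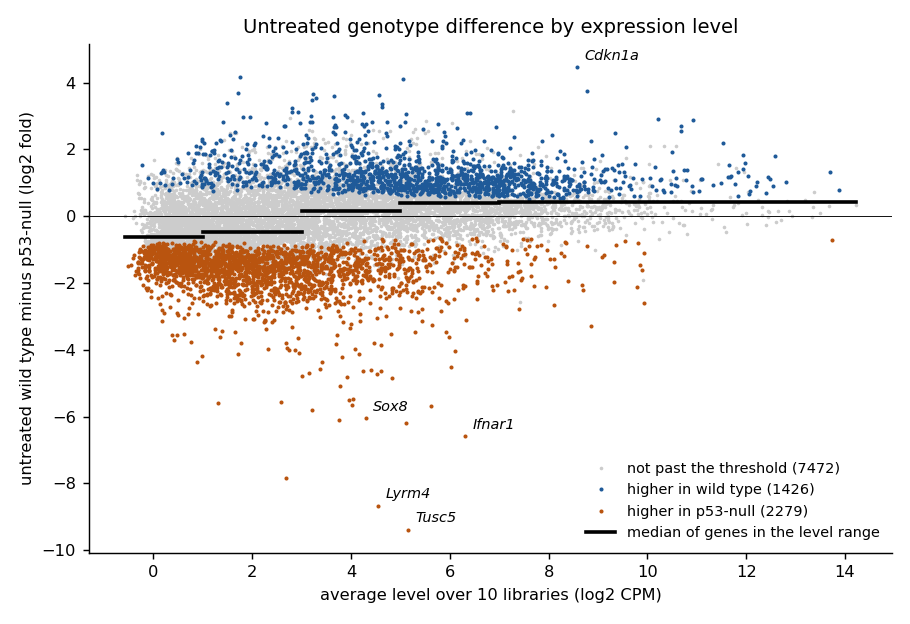
Log2 fold of untreated wild type over untreated p53-null cells against the average log2 CPM of each of 11177 genes, with calls in colour (1426 higher in wild type, 2279 higher in p53-null) and black bars for the median in each range of levels. The bars climb from -0.62 under a log2 CPM of 1 to 0.42 at 7 and above.

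Gene groups differed between the untreated genotypes in both directions, and these list tests too do not separate a list from the level of its genes. Ribosomal protein genes were higher in wild type for 25 of 69 members and lower for 1 (28 and 1 adjusted over the list alone), with a median of 0.89 (camera adjusted p = 3e-07, and adjusted p = 0.278 with an estimated correlation). Rpl13a stood at 1.19 (SE 0.18) and Rps21 at 1.39 (SE 0.22), while Rpl23a was lower at -3.30 (SE 0.19). Reads of these genes can be shared with processed pseudogenes. Oxidative phosphorylation genes had 16 of 57 members higher and 6 lower (17 and 6 adjusted over the list alone), a median of 0.42 (adjusted p = 0.011, and adjusted p = 0.132 with an estimated correlation). Examples were Ndufs3, a complex I subunit gene, at 1.47 (SE 0.19) and Cox6b1, a complex IV subunit gene, at 1.31 (SE 0.18). The p53 targets had 10 of 43 higher and 3 lower (9 and 3 adjusted over the list alone), with a median of 0.38 (adjusted p = 0.00838, and adjusted p = 0.132 with an estimated correlation). Psrc1, a spindle protein gene, was among the former at 1.52 (SE 0.21), and the lower ones were Polk (-1.10), Aldh4a1 (-1.60) and Prkab1 (-0.89). The medians of these lists kept their sign under 3 other scalings of the libraries. They lay at least 0.93, 0.46 and 0.41 above the median of all genes for ribosomal protein genes, oxidative phosphorylation genes and p53 targets. Another scaling shifts all genes nearly alike, so this distance could hardly change and gives the lists no separate support.

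Interferon response genes were lower in wild type for 12 of 32 members and higher for 0 (12 and 0 adjusted over the list alone), with a median of -0.96 (adjusted p = 0.0115, and adjusted p = 0.779 with an estimated correlation). Irgm1, an interferon-induced GTPase gene, was lower at a log2 fold of -2.26 (SE 0.37), and the interferon-induced Isg15 at -2.23 (SE 0.37), with 17.4 CPM in wild type and 82.1 CPM in p53-null cells. Immediate early genes were lower for 16 of 42 and higher for 1 (17 and 1 adjusted over the list alone), with a median of -0.82 (adjusted p = 0.0143, and adjusted p = 0.368 with an estimated correlation). They included Myc at -2.84 (SE 0.39) and Egr1 at -2.45 (SE 0.38), and the member higher in wild type was Gadd45g at 0.88 (SE 0.23). Genes of G2 and mitosis were lower for 20 of 55 and higher for 0 (20 and 2 adjusted over the list alone), with a median of -0.66 (adjusted p = 0.031, and adjusted p = 0.779 with an estimated correlation). Ckap2 stood at -3.24 (SE 0.35) and Kif20b, a mitotic kinesin gene, at -2.47 (SE 0.38). With library size alone the mitotic list no longer passed (adjusted p = 0.0646), and with fry neither it (adjusted p = 0.0754) nor the interferon list (adjusted p = 0.113) did.

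Some markers of other cell types passed between untreated genotypes, where 3705 of 11177 genes did, while none of their lists passed as reported. Of the blood and macrophage markers, Fcgr3, an Fc receptor gene, was higher in wild type at 3.70 (SE 1.26, adjusted p = 0.0468) and Tyrobp at 2.18 (SE 0.76, adjusted p = 0.049). Both differences rest mostly on untreated wild-type replicates 2 and 3. Fcgr3 stood at 1.19, 24.5 and 43 CPM in replicates 1, 2 and 3, and at 0.336 and 0.571 CPM in untreated p53-null libraries. Tyrobp stood at 26.9, 119 and 120.9 CPM, and at 16 and 15.5 CPM. The blood and macrophage list had a median of 1.03 and did not pass (adjusted p = 0.0592, and adjusted p = 0.789 with an estimated correlation). Of its 14 members 2 were higher, and 0 adjusted over the list alone. It passed with library size alone at 0.0151 and with the replicate block at 0.0187, where the numbers pair libraries of different genotypes. Skeletal muscle markers (1 higher, 2 lower of 13) and neural and glial markers (2 higher, 3 lower of 9) went both ways, with the same counts adjusted over the list alone. The sex marker Xist, expressed from an inactive X chromosome, stood at 11.9 CPM in wild type and 0.858 CPM in p53-null cells, so sex went in part with genotype.

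The overlap of the doxorubicin response with the untreated genotype difference asks whether genes raised by damage also need p53 before damage. Cdkn1a, Mdm2, Ptprv and Psrc1 were in both sets, rising with doxorubicin and standing higher in untreated wild type. In all 112 genes did so, against 114.3 for independent lists, and 47 with library size alone, against 40.4. A further 182 genes, Ckap2 among them, rose with doxorubicin and were lower in untreated wild type, against 182.7. Of the genes that fell with doxorubicin, 186 were higher in untreated wild type, against 65.1, and 18 were lower, against 104. The numbers for independent lists take no account of expression level, with which the 2 folds ran in opposite directions. From an average log2 CPM under 1 to 7 and above, the median went from 0.24 to -0.07 with doxorubicin. Between untreated genotypes it went from -0.62 to 0.42. How much of these departures comes with level was not tested. Both comparisons use the 3 untreated wild-type libraries, and chance in them pushes the 2 folds apart. The Pearson correlation across genes was -0.288, against -0.447 in 100 simulations with unchanged groups and independent libraries, and -0.313 in 100 with wild-type numbers paired at their mean correlation of 0.51. The covariance was -0.239, against -0.07 and -0.034. The simulations gave means of 0 and 0.01 genes in the group of 186, which does not measure the share that the common libraries add to real changes.

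The list of p53 binding sites held 4785 distinct peaks on 20 chromosomes, with an enrichment from 3 to 769.8 and a median of 15.3. There is 1 list and no replicate, so these values carry no error. The peaks ranked 1 and 2 lay at position 13549008 of chromosome 8, with an enrichment of 769.8, and position 111963475 of chromosome 12, with 612.6, on build mm9. The next 3 lay at 90881551 of chromosome 10 (167.3), 156903457 of chromosome 1 (160.3) and 29227883 of chromosome 17 (171.6). An enrichment of 100 or more was listed for 125 peaks, 10 or more for 3188, and under 5 for 488. Chromosome 11 held 398 peaks (8.3%) and chromosome X held 59 (1.2%). Another peak lay within 10 kb of 22.9% of the peaks. No gene annotation on mm9 was at hand, so no peak was given to a gene and binding was not set against expression.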

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

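The interaction test behind these values was planned, while its form in limma-trend was chosen after the values had been examined. Each result here stands out because the response to doxorubicin differed between wild-type and p53-null cells by that test, and values are wild-type minus p53-null log2 folds. In all, 261 genes differed.

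Among the p53 targets of the fixed panel, the difference was 2.05 for Cdkn1a, 2.67 for Mdm2, 3.3 for Ccng1, 2.96 for Bbc3 and 2.85 for Pmaip1. Pmaip1 had 1 read over the untreated wild-type libraries, so its fitted value depends on the 0.5 CPM added. Genes stronger in wild type also included Hyal1 at 3.72, Ckap2 at 3.62, Dcxr at 3.59, Scx at 3.57, 4432412L15Rik at 3.35 and Iffo1 at 3.24. Further values were 3.14 for Cox6b2, 3.12 for Ass1, which encodes argininosuccinate synthase, 3.12 for Ptp4a3, 2.83 for Nat6, 2.82 for Mmp15 and 2.32 for Icam1.

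Genes with the lower wild-type response included Dhodh, encoding a pyrimidine synthesis enzyme, at -2.32, and 2810433K01Rik at -2. Of the 50 genes with a lower value, 45 had a p53-null fold above 0, none past the threshold. The difference was -1.91 for Cmklr1, -1.88 for the exosome gene Exosc8, -1.85 for the protease gene Rce1 and -1.74 for Sephs1. Nsmce4a, of the SMC5/6 complex, stood at -1.74, Ftsj2 at -1.73 and Tk1 at -1.72.

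As lists, p53 targets had a median difference of 1.99, immediate early genes of 0.8, DNA replication genes of -0.38 and ribosomal protein genes of -0.34. All 4 passed camera, and only the p53 targets passed with an estimated correlation.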

How the results depend on the processing

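The deposited values, added CPM, cyclic loess, thinning, the p53-null libraries numbered 2 and the peak threshold were alternatives chosen after the results were seen. Thinning as a test of depth over all calls between untreated genotypes was set before the data were examined. Of the alternative values of named genes, 630 of 647 kept direction and side of the threshold for doxorubicin in wild type, 158 of 166 in p53-null, 450 of 597 for the difference of responses and 544 of 621 between untreated genotypes. Where a cause is not given below, the cause was not tested. A stricter adjusted p under 0.01 by construction gave 534 genes in wild type, 73 for the difference, 1095 between untreated genotypes and 33 in the overlap (112 as reported). With the replicate block, which rests in part on a p53-null pair whose sex markers differed, 2600 and 1076 genes passed in wild type and for the difference. Fitting only the groups compared, with fewer libraries to estimate the spread, gave 784 in wild type. Upper quartile scaling gave 169 for the difference, library size alone gave 47 in the overlap, and cyclic loess gave 2469 between untreated genotypes. Without a filter on low levels 2 genes passed in p53-null cells. Without the p53-null libraries numbered 2, whose lone partners are assumed to vary like the other groups, 779, 0 and 216 genes passed in wild type, for the difference and between untreated genotypes. With the correlation estimated, 2 of 22 list calls remained. With fry, which sets members against no change, 12 of the 22 remained and 8 other list tests passed. An enrichment of 10 or more kept 3188 of 4785 peaks by construction.

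Leaving out each library gave 712 to 1459 genes in wild type, 0 to 1 in p53-null, 38 to 320 for the difference and 422 to 4226 between untreated genotypes. Genes that turned sign did so without passing the threshold in either fit. In p53-null cells, leaving out each library gave -0.006 to 0.308 for Mdm2, -0.395 to 0.098 for Ccng1, -0.46 to 0.29 for Bax, where a value of 0.002 came without treated p53-null replicate 2, and -0.021 to 0.109 for Pmaip1. Ccng1 there was 0.036 with thinned libraries and 0.008 without the p53-null libraries numbered 2, and Pmaip1 was -0.039 without them. Between untreated genotypes Bax ran from -0.559 to 0.214 with each library left out, and Pmaip1 was 0.194 with cyclic loess. A second count test and the overlap of peaks with expression calls, with its alternatives, were not run. Depth limits genes of few reads, such as Pmaip1 and Fas in untreated wild type.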

Other observations

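The tests of library scaling, of a distortion with level, of a wild-type library under a p53-null label, of low-level genes after thinning, of further thinned draws, of small RNAs, of swapped labels, of Trp53 reads and of another embryo were chosen after the results were seen. Some stress and lipid genes also passed in treated wild type, where 1406 of 11177 genes did, while their lists did not pass camera. Of 35 unfolded protein and integrated stress genes 2 rose and 4 fell (2 and 4 adjusted over the list alone). Sesn2, encoding the stress protein sestrin 2, rose by 2.31 (SE 0.36), while Trib3, Chac1 (-1.90, SE 0.41) and Xbp1 (-1.46, SE 0.29) fell (list adjusted p = 0.463). Of 31 sterol biosynthesis genes 1 rose and 5 fell (1 and 5 adjusted over the list alone), among them Fdft1, encoding squalene synthase, at -1.51 (SE 0.23). This list stood at camera adjusted p = 0.0774, and passed with fry at adjusted p = 0.0334. Of 51 extracellular matrix and fibroblast genes 1 rose and 6 fell (1 and 6 adjusted over the list alone), such as the growth factor receptor gene Pdgfrb at -1.50 (SE 0.34, list adjusted p = 0.697). Of 31 NRF2 antioxidant genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), with Hmox1, encoding heme oxygenase 1, at 1.67 (SE 0.36). The NRF2 list stood at camera adjusted p = 0.103, and passed with fry at adjusted p = 0.0197. NF-kB and inflammatory genes had 4 of 29 higher and 2 lower (6 and 2 adjusted over the list alone, list adjusted p = 0.697), and immediate early genes had 5 of 42 higher and 5 lower (10 and 6 adjusted over the list alone, list adjusted p = 0.687). The latter included Fosl1 at 1.12 (SE 0.20) and Cyr61 at -1.34 (SE 0.18).

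DNA repair genes went both ways in treated wild type, with 3 of 51 higher and 5 lower (3 and 5 adjusted over the list alone, list adjusted p = 0.291). Ercc5, an excision repair nuclease gene, rose by 1.90 (SE 0.30), Msh6, a mismatch repair gene, rose by 1.66 (SE 0.33), and Ung, encoding uracil glycosylase, fell with a log2 fold of -1.35 (SE 0.28). Ribosomal protein genes had 2 of 69 higher (1 adjusted over the list alone, list adjusted p = 0.702) and oxidative phosphorylation genes 2 of 57 (1 adjusted over the list alone, list adjusted p = 0.621). With fry the oxidative phosphorylation list passed at adjusted p = 0.0242. Skeletal muscle markers and neural and glial markers had 0 members past the threshold by limma-trend. Among markers in lists too small to test, Eng, an endothelial receptor gene, rose by 1.39 (SE 0.29), and of the epithelial markers Krt19 stood at 0.94 (SE 0.40, adjusted p = 0.169).

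Between untreated genotypes other lists also went both ways and did not pass by limma-trend. Core autophagy genes had 6 of 42 higher and 8 lower in wild type (6 and 9 adjusted over the list alone, list adjusted p = 0.697), with Atg4b at 1.41 (SE 0.23) and Atg12 at -2.19 (SE 0.34). Lysosome genes had 10 of 48 higher and 6 lower (10 and 6 adjusted over the list alone, list adjusted p = 0.0592). They passed with the replicate block (adjusted p = 0.0271), where the numbers pair libraries of different genotypes. The lysosome list stood at camera adjusted p = 0.649 with an estimated correlation and no block. Examples were Npc2 at 1.46 (SE 0.21) and Ppt1 at -1.80 (SE 0.36). DNA replication genes had 2 of 55 higher and 11 lower (2 and 10 adjusted over the list alone, list adjusted p = 0.688), and extracellular matrix genes 8 of 51 higher and 14 lower (12 and 14 adjusted over the list alone, list adjusted p = 0.726). In the latter S100a4, a calcium-binding protein gene of fibroblasts, stood at 2.69 (SE 0.29) and the fibronectin gene Fn1 at -1.93 (SE 0.30). Hyou1, an endoplasmic reticulum chaperone gene, was lower in wild type at -4.03 (SE 0.20), and Sod2, encoding mitochondrial superoxide dismutase, at -4.59 (SE 0.57).

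Of the 10 splits of the 6 wild-type libraries into 3 and 3, only 1, the real one, gave as many calls as treatment did, with 1406 genes, and the highest other gave 4. The other 3 splits that part all 3 same-number pairs gave 0 genes each by limma-trend. With 10 splits the share cannot fall under 0.05.

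Genes of low level were mostly higher in untreated p53-null cells: of the calls at average log2 CPM under 3, 1571 were higher there and 235 lower, a share of 87%, against 61.5% over all calls. At low level, deeper p53-null libraries are argued against as the whole source. Thinning every library to equal reads left 86.7% there, and 20 further draws left 84.7% to 88%. Over all calls thinning left 60.2% and the further draws 56% to 62.2%. By the limits set before the data were examined, this decides nothing on depth. At low level 3 other scalings gave 83.6%, 91.8% and 96%. They shifted the median of all genes, wild type minus p53-null, by 0.09, -0.16 and -0.35. The medians were -0.62 under an average log2 CPM of 1 and -0.49 at 1 to 3. No scaling tried came near removing these, so the scalings cannot decide on a common factor at low level. A distortion of the libraries that depends on level cannot be told apart from a difference in expression. Cyclic loess left 50.4% at low level (540 higher and 532 lower in p53-null), but it removes any trend with level, of either origin, by construction. Over all calls the 3 scalings gave 54.4%, 73.3% and 86.6%, so the size of that share moved with the scaling, and the part of a common factor cannot be told apart because no value shows which scaling is right. Carry-over of nuclear RNA cannot be told apart from other sources with so few genes. The 6 small nuclear and nucleolar RNAs tested, which lack poly(A) tails, had a median of 1.26 higher in p53-null, at percentile 97.08 of matched lists. Rmrp at 2.53 and Snora68 at 1.27 passed the threshold, while Rnu1b2 (1.40), Snord82 (1.24), Rpph1 (-0.09) and Snord22 (-1.16) did not. The summed CPM of 32 such genes overlapped, at 37.9, 8.98 and 13.1 in untreated wild type and 61.8 and 34.1 in untreated p53-null libraries. A library batch cannot be told apart from genotype here, and sex markers went in part with genotype. A biological difference between the genotypes stays open and untested.

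More Trp53 reads in p53-null than in wild-type cells raise the question of the labels. Swapped genotype labels are argued against by the doxorubicin response, since the smaller of the Cdkn1a and Mdm2 interactions was 6.64 standard errors above 0. Reads from a part of the gene outside the deletion could account for the presence of Trp53 reads in p53-null cells. Wild-type cells hold that part too, so its presence alone does not give the log2 excess of 1.62. No read positions were used here, and the source of the excess cannot be told apart.

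The sex markers of treated p53-null replicate 2 differed from those of untreated p53-null replicate 2. The treated library had 15 reads of 4 Y-linked genes and 399 of Xist, and the untreated one had 216 and 15. A wild-type library under a p53-null label is argued against, since 94% of 100 genes that separate the untreated genotypes lay nearer to p53-null. Cells of another embryo cannot be told apart from other sources, since the CPM of Y-linked genes, 20.1 times higher in the untreated library, is the difference that raised the question. In wild type, replicate 1 had 166 and 147 Y-linked reads untreated and treated, and replicates 2 and 3 had 0 to 9.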
